A study of Mus musculus with 6 samples.

How the data were processed

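The series holds RNA-seq libraries labelled as whole brain from C57BL/6 mice, 3 mock-irradiated and 3 cranially irradiated with 10 Gy of X-rays, taken 30 days after the exposure. Per the labels' protocols, ribosomal RNA was removed, stranded libraries were made from total RNA, and single-end reads of 75 nucleotides were sequenced to about 30 to 40 M reads per library. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped total of a library), in 1 table with 1 column per library. TopHat, Cufflinks, Cuffdiff and the mouse build mm10 are named in the submitters' processing notes. Their versions, settings and roles, the gene annotation and the total used to scale each library are not given in the sources used here.

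The table held 23057 gene symbols after 1 leftover header line had been removed, and 3378 of them were listed at 0 in all 6 libraries. The deposited FPKM summed to between 472450 and 625782 per library. FPKM values are not counts, so no count model was used. Among genes under 0.05 FPKM, no single ratio to mock library 1 was shared by more than 6.05% of the genes in any other library. The relative depth could therefore not be recovered, and the depth beyond the approximate read number in the labels is unknown. An exact 0 can be a failed estimate in such tables, so a gene at 0 is described as listed at 0.

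Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 14585 in all. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with group as the only term, a mean-variance trend in the empirical Bayes step, two-sided p-values and Benjamini-Hochberg adjustment. An adjusted p under 0.05 was a call. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. A comparison of 3 animals with 3 cannot give an exact permutation p under 0.1, so all p-values come from limma. The labels give each mouse a replicate number but do not say that equal numbers share a litter, cage or day.

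Before the data were examined, the tests, the filter, the pseudocount and 48 gene lists were fixed. The lists stand for pathways, cell types, brain regions and technical checks, and 44 of them had the 5 tested members needed for a list test. The list test was camera in limma, which compares a list's genes with all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 44 lists. It was repeated with a correlation estimated for each list, which in limma also limits the test to the residual degrees of freedom, here 4. The fry test in limma, which asks whether a list's genes move one way without comparing them with other genes, was a further alternative. Calls within a list were counted over all genes tested and also adjusted over the list alone.

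The genes named were chosen by a rule fixed at the same stage. It took the 12 largest changes in each direction among called genes whose irradiated libraries all lay outside the mock range, 19 genes of interest whatever their result, and up to 4 members of each list with the smallest p. Genes chosen after their values were seen are marked as such, and a withheld gene is not reported here. A further 8 lists of brain region markers were made after the data were seen. They describe the libraries, and the telencephalon list also gave a covariate. Coordinates are those of the RefSeq annotation of GRCm38.p6, the assembly that mm10 represents.

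Alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter on low values, a mean of at least 1 FPKM, median centring, quantile normalization, robust empirical Bayes, library weights, the replicate number as a block, leaving out each library, an adjusted p under 0.1 and a minimum log2 change of 0.3. Alternatives added after the data were seen were leaving out mock 2 and irradiated 1 together, a covariate made of 8 telencephalic genes, and a lowess correction (span 0.3) of each library for transcript length and GC content. The 18 settings given for lists are these alternatives of the data or the fit, each with the preset correlation. The longest transcript per gene in GENCODE gave a length and GC content for 96.3% of the tested genes. The gene test was tested on simulated data for this comparison with 14585 genes, of which 200 were changed: 41% of those changed by 1 on the log2 scale and 93% of those changed by 2 were called, and 6.94% of all calls were unchanged genes. The simulated noise was independent between genes, so these shares need not hold where genes move together.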

Results

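RNA was measured in brains of C57BL/6 mice 30 days after a single cranial X-ray dose of 10 Gy, or after mock irradiation, with 3 mice in each group. The labels call the samples whole brain. Region markers, given below, differed strongly between libraries of the same group, so the libraries may not all hold the same parts. The title of the series concerns senescence induced by radiation in the tissue around brain tumors, so the comparison asks which genes, and among them senescence and inflammation genes, differ in normal brain 1 month after irradiation. Each library is named by its group and replicate number. Between 14362 and 14583 genes reached 0.5 FPKM in a library, and the labels give about 30 to 40 M reads per library. Spearman correlations of FPKM across the tested genes were 0.972 to 0.987 between mock libraries, 0.964 to 0.984 between irradiated libraries and 0.913 to 0.963 between the groups.

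The irradiated libraries had more RNA of interferon-response, antigen-presentation and microglial genes and less of oligodendrocyte-precursor and myelin genes. The widest differences, however, were in genes that mark regions of the brain. No libraries of the groups overlapped on the cerebellum list, so regional makeup cannot be told apart from irradiation for any of these differences. Of 14585 genes tested, 508 were higher and 618 were lower after irradiation (limma, adjusted p under 0.05), and every one of them had its 3 irradiated libraries outside the range of the 3 mock libraries. Among all tested genes 31.5% were separated in this way, against 10% by chance. Of the 44 gene lists tested with camera, 11 were higher and 5 were lower. No list passed with an estimated correlation between genes (smallest adjusted p = 0.55, with 1 list at an unadjusted p under 0.05), and fry called 3 lists higher (hippocampus, interferon and p53 targets) and 2 lower (cerebellum and oligodendrocyte precursors). For the other 11 lists that passed camera the fry adjusted p was 0.066 to 0.44. Of the 10 ways to split the 6 libraries into 3 and 3, 4 called at least as many lists as the real grouping, but only the real grouping called more than 12 genes. Leaving out mock 1, mock 2, mock 3 or irradiated 3 changed the gene counts by over 1.5 times in both directions, to 187 higher and 254 lower, 205 and 298, 309 and 342, and 147 and 260 respectively.

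Genes of the cerebellum and hindbrain were far lower in the irradiated libraries. Of 25 cerebellum genes, 22 fell and 0 rose (23 fell when adjusted over the list alone, and 0 rose at an unadjusted p under 0.05), with a median log2 change of -2.43 (camera adjusted p = 1.31e-24, and adjusted p = 0.55 with an estimated correlation). Gabra6, the GABA-A receptor subunit of cerebellar granule cells (chromosome 11, 42306437 to 42321072), had 73.8, 127 and 52.9 FPKM in the mock libraries and 1.39, 0 and 0.02 FPKM in the irradiated ones, where 0 is the value listed. Pcp2, a Purkinje cell gene, was at 500.5 ± 30.2 FPKM in mock and 8.83 ± 11.6 FPKM in irradiated libraries (SD, n = 3 each; log2 change -6.54, SE 0.73, limma adjusted p = 0.0017). Slc6a5, the glycine transporter of brainstem and spinal cord neurons, had a log2 change of -4.77 (SE 0.22), and Hes3, a transcriptional repressor, had one of -4.15 (SE 0.18). Hoxb6, a gene of the hindbrain and spinal cord, was at 7.88, 11.4 and 18.7 FPKM in mock and was listed at 0 in each irradiated library.

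Hippocampal and excitatory neuron genes were higher, while other forebrain lists were mixed. Of 24 hippocampus genes, 15 rose and 0 fell (17 rose when adjusted over the list alone, and 0 fell at an unadjusted p under 0.05), with a median log2 change of 1.15 (camera adjusted p = 5.62e-12, and adjusted p = 0.55 with an estimated correlation). C1ql2, a synaptic organizer of dentate granule cells (chromosome 1, 120340582 to 120343174), went from 3.33 ± 0.66 to 35.0 ± 4.99 FPKM (SD, n = 3; log2 change 3.22, SE 0.19, limma adjusted p = 0.00019). Spink8 had a log2 change of 3.43 (SE 0.29) and Fibcd1 one of 2.72 (SE 0.21). The excitatory neuron list had 7 of 25 members higher and 0 lower (14 higher when adjusted over the list alone), Neurod6 among them with a log2 change of 1.72 (SE 0.23), and a median of 1.06 (camera adjusted p = 1.00e-07, and adjusted p = 0.66 with an estimated correlation). Over 18 settings that median ranged from 0.55 to 1.23, with 0.55 without mock 2. The striatum list had 2 members higher and 1 lower of 17 (7 and 1 when adjusted over the list alone), with a median of 0.47 (camera adjusted p = 0.032, and adjusted p = 0.56 with an estimated correlation). It passed in 14 of 18 settings, and not with a mean of at least 1 FPKM (adjusted p = 0.059), with no filter (0.14), without irradiated 3 (0.058) or with the length and GC correction (0.089). The olfactory bulb list had 1 member higher and 2 lower of 19 (1 and 3 when adjusted over the list alone; median -0.70, camera adjusted p = 0.21), and the hypothalamus list 2 higher and 2 lower of 17 (4 and 2 when adjusted over the list alone; camera adjusted p = 0.24). They passed in 5 and 3 of 18 settings. Slc6a3, the dopamine transporter, was at 0.59, 3.37 and 0.34 FPKM in mock and at 21.2, 43.2 and 23.3 FPKM in irradiated libraries.

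Region markers also differed between libraries of the same group. Over 8 telencephalic genes, the library medians ranged over 3.63 on the log2 scale among mock libraries and over 0.85 among irradiated ones. Doc2g, a gene of olfactory bulb output neurons, was at 94.4, 6.22 and 117.7 FPKM in mock and at 123.4, 3.96 and 4.26 FPKM in irradiated libraries. Doc2g and the region lists in the plot were chosen after their values were seen. With mock 2 and irradiated 1 left out together, 620 genes were higher and 672 were lower. This did not even out the regions. Mock 1 and mock 3 lay at 1.48 and 1.52 on the list of olfactory bulb output neurons, and irradiated 2 and 3 at -1.43 and -1.58.

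**Figure D1:**
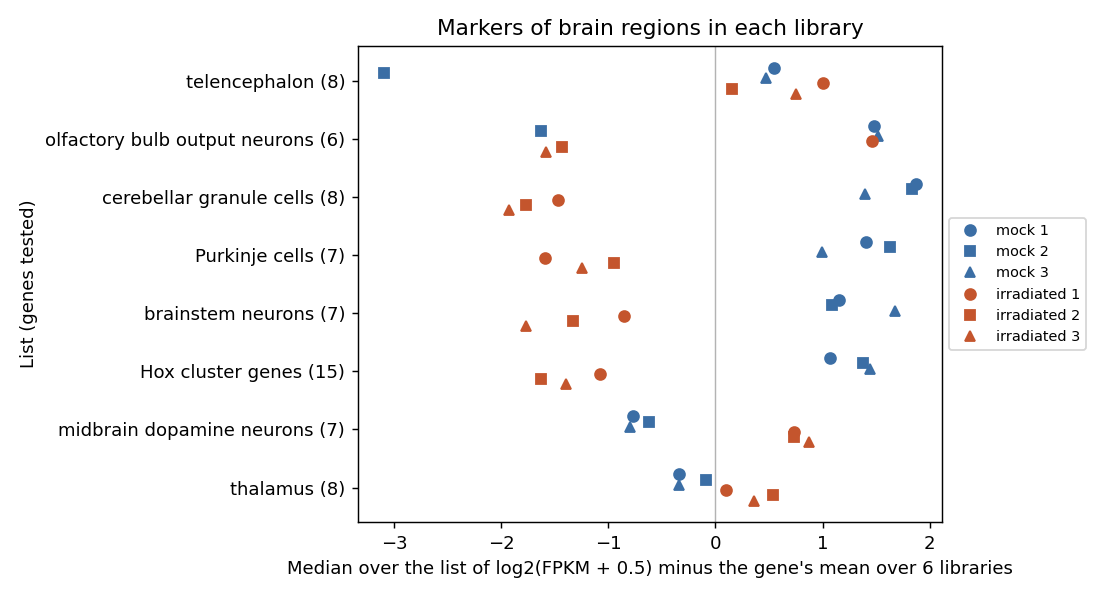
Each point is 1 library's median over the genes of a region list of log2(FPKM + 0.5) minus the gene's mean over 6 libraries; blue points are mock and orange points irradiated libraries, and shapes give the replicate number. Cerebellar, brainstem and Hox lists lie higher in all mock libraries, the midbrain dopamine (median log2 change 1.53) and thalamus (0.57) lists lie higher in all irradiated libraries, the telencephalon list sets mock 2 (-3.09) apart, and the olfactory bulb list is high in mock 1, mock 3 and irradiated 1.

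Interferon-response and antigen-presentation genes were higher after irradiation. Of 37 type I interferon response genes, 8 rose and 0 fell (12 rose and 1 fell when adjusted over the list alone), and the median log2 change was 0.33 (camera adjusted p = 6.26e-06, and adjusted p = 0.55 with an estimated correlation; fry adjusted p = 0.042). The library medians of this list were -0.18, -0.18 and -0.15 in mock and 0.25, 0.28 and 0.019 in irradiated libraries, so irradiated 3 lay closest to mock. Ifi27l2a, an interferon-induced gene (chromosome 12, 103433873 to 103443680), was at 6.60 ± 1.21 FPKM in mock and 27.2 ± 5.12 FPKM in irradiated libraries (SD, n = 3; log2 change 1.96, SE 0.19, limma adjusted p = 0.0011). Bst2, which tethers viruses at the cell surface, had a log2 change of 1.36 (SE 0.15). Irf7, a transcription factor that drives interferon expression, had one of 1.27 (SE 0.17), and Lgals3bp one of 1.42 (SE 0.22). The MHC class I list had 5 of 19 members higher and 0 lower (10 higher when adjusted over the list alone; median 0.61, camera adjusted p = 0.00028, and adjusted p = 0.55 with an estimated correlation). The MHC class II list had 2 of 7 higher and 0 lower (5 higher when adjusted over the list alone; median 1.46, camera adjusted p = 0.0019, and adjusted p = 0.69 with an estimated correlation). The class II median was 0.68 without a filter and 0.92 without irradiated 1, and by library it was 1.46 in irradiated 1 but 0.22 and 0.19 in irradiated 2 and 3. H2-DMa, which loads peptides on class II molecules, went from 3.72 ± 0.41 to 12.2 ± 3.50 FPKM. H2-Aa, a class II chain, had a log2 change of 1.56 (limma adjusted p = 0.046), which was not called without mock 1, 2 or 3 or irradiated 3 (largest adjusted p = 0.12). In the same libraries the cerebellum list had a median log2 change of -2.43.

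Microglial genes were higher as well. By library the homeostatic microglia list median was -0.28, -0.36 and -0.17 in mock and 0.42, -0.039 and 0.29 in irradiated libraries. Of 30 homeostatic microglia genes, 6 rose and 0 fell (14 rose when adjusted over the list alone), with a median log2 change of 0.50 (camera adjusted p = 4.28e-05, and adjusted p = 0.69 with an estimated correlation). Fcrls was at 9.004 ± 2.07 FPKM in mock and 18.9 ± 2.54 FPKM in irradiated libraries, and Laptm5, a lysosomal membrane protein of leukocytes, at 10.5 ± 2.33 and 21.4 ± 2.53 FPKM (SD, n = 3). Both calls were lost without mock 1, without mock 2 or without irradiated 3 (largest adjusted p = 0.086 and 0.070). Aif1, a microglial marker also called Iba1, had a log2 change of 0.87 (SE 0.25, limma adjusted p = 0.074), and was called without irradiated 2 (adjusted p = 0.027). The disease-associated microglia list had 7 of 25 members higher and 0 lower (9 and 1 when adjusted over the list alone) and did not pass camera (adjusted p = 0.071). Its median was -0.06 and its mean 0.28. It passed in 3 of 18 settings, with the smallest adjusted p without a filter (0.011, median 0.15). Lpl, a lipase of that list, went from 1.43 ± 0.19 to 5.07 ± 1.39 FPKM. Of the 25 lymphocyte genes in the table only 4 were tested, too few for a list test, and 3 of them rose (4 when adjusted over the list alone). Without a filter the list had a median log2 change of 0.038 and did not pass (camera adjusted p = 0.078). Zap70, a kinase of T cell receptor signalling, went from 0.97 ± 0.27 to 3.34 ± 0.18 FPKM. C4b, a complement gene, had a log2 change of 1.14 (SE 0.19), not called without irradiated 3 (adjusted p = 0.052). The complement list did not pass (2 higher and 1 lower of 17, 3 and 1 when adjusted over the list alone; camera adjusted p = 0.24). The telencephalic and cerebellar markers given above differed between the same libraries.

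Senescence genes gave a mixed picture. Cdkn1a, which encodes the cell-cycle inhibitor p21 (chromosome 17, 29090979 to 29100722), was at 20.0, 22.01 and 28.3 FPKM in mock and at 46.8, 37.4 and 29.8 FPKM in irradiated libraries. Its log2 change of 0.68 (SE 0.21, 95% interval 0.20 to 1.16) did not pass the adjustment (limma adjusted p = 0.087). Of 22 cell-cycle inhibitors and senescence markers, 0 rose and 1 fell (0 when adjusted over the list alone, and 2 were higher and 3 lower at an unadjusted p under 0.05), with a median log2 change of 0.05 (camera adjusted p = 0.97). The 1 that fell was Cdkn1b, a cell-cycle inhibitor, with a log2 change of -0.94 (SE 0.23, limma adjusted p = 0.043). Of 32 p53 targets, 3 rose and 0 fell (3 rose when adjusted over the list alone), with a median log2 change of 0.15 (camera adjusted p = 0.014, and adjusted p = 0.55 with an estimated correlation; fry adjusted p = 0.042). The 3 members were Psrc1, a spindle protein, at 0.90 ± 0.61 and 7.11 ± 2.43 FPKM, Plk2, a kinase that neuronal activity also induces, at 14.5 ± 5.79 and 52.6 ± 18.6 FPKM, and Apaf1, the core of the apoptosome, at 1.39 ± 0.15 and 4.04 ± 1.34 FPKM. In mock 2, the library with the lowest telencephalon list, Psrc1 was at 0.22 FPKM and Plk2 at 8.08 FPKM, the lowest value of each, and the region markers above differed between the groups as well. Plk2 was not called without irradiated 3 (adjusted p = 0.056), nor Apaf1 without any 1 of the mock libraries (largest adjusted p = 0.060). Mdm2, the p53 ubiquitin ligase, had a log2 change of -0.10 (95% interval -0.45 to 0.25), and Trp53 had one of 0.38 (adjusted p = 0.21). Cdkn2a, which encodes p16, was below the filter, at 0, 0 and 0.13 FPKM in mock and 0.26, 0.24 and 0.47 FPKM in irradiated libraries (limma adjusted p = 0.059 without a filter). Cdkn2b had a log2 change of -0.16 (adjusted p = 0.71).

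Secreted senescence-associated factors moved in both directions. Of 52 tested, 6 rose and 3 fell (7 and 6 when adjusted over the list alone), and the median log2 change was 0.05 (camera adjusted p = 0.47). Cxcl10, an interferon-induced chemokine, rose from 0.46 ± 0.04 to 2.19 ± 0.74 FPKM (SD, n = 3; log2 change 1.46, SE 0.23, limma adjusted p = 0.0083). Tnfrsf11b, a decoy receptor for RANKL, fell from 2.24 ± 0.09 to 0.63 ± 0.19 FPKM. Hgf, hepatocyte growth factor, had a log2 change of 0.64 (SE 0.37, adjusted p = 0.31; from 0.21 without irradiated 3 to 0.94 without irradiated 1), with 0.76, 0.34 and 0.64 FPKM in mock and 0.60, 0.87 and 2.54 FPKM in irradiated libraries. Its receptor Met had one of 0.72 (SE 0.27, adjusted p = 0.14). Gdf15 had one of -0.13 (adjusted p = 0.81), and Il6 stayed at or below 0.23 FPKM in each library. The cell cycle and mitosis list had 2 of 31 members lower and 0 higher (2 and 0 when adjusted over the list alone; 4 higher and 5 lower at an unadjusted p under 0.05), with a median of -0.04 (camera adjusted p = 0.79). Spag5, a spindle protein, was the lower of the 2 with a log2 change of -1.17 (SE 0.18). Mki67 and Top2a, proliferation markers, were below the filter. Mki67 was at 0.05, 0.03 and 0.08 FPKM in mock and at 0.14, 0.09 and 0.15 FPKM in irradiated libraries. Top2a was at 0.16, 0.06 and 0.08 FPKM in mock and at 0.14, 0.21 and 0.25 FPKM in irradiated libraries. Without a filter neither was called (limma adjusted p = 0.17 for Mki67 and 0.24 for Top2a). Among BCL-2 family genes, Bcl2l1, which encodes BCL-XL, had a log2 change of 0.40 (adjusted p = 0.21), Bcl2 one of -0.01 (0.97) and Mcl1 one of -0.31 (0.30). The anti-apoptotic list had 0 of 9 called in limma (1 lower at an unadjusted p under 0.05; camera adjusted p = 0.74). The pro-apoptotic list had 2 higher and 1 lower of 12 (4 and 2 when adjusted over the list alone; camera adjusted p = 0.45), with Hrk at 1.91 (SE 0.26) and Bmf at -1.14 (SE 0.18).

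**Figure D2:**
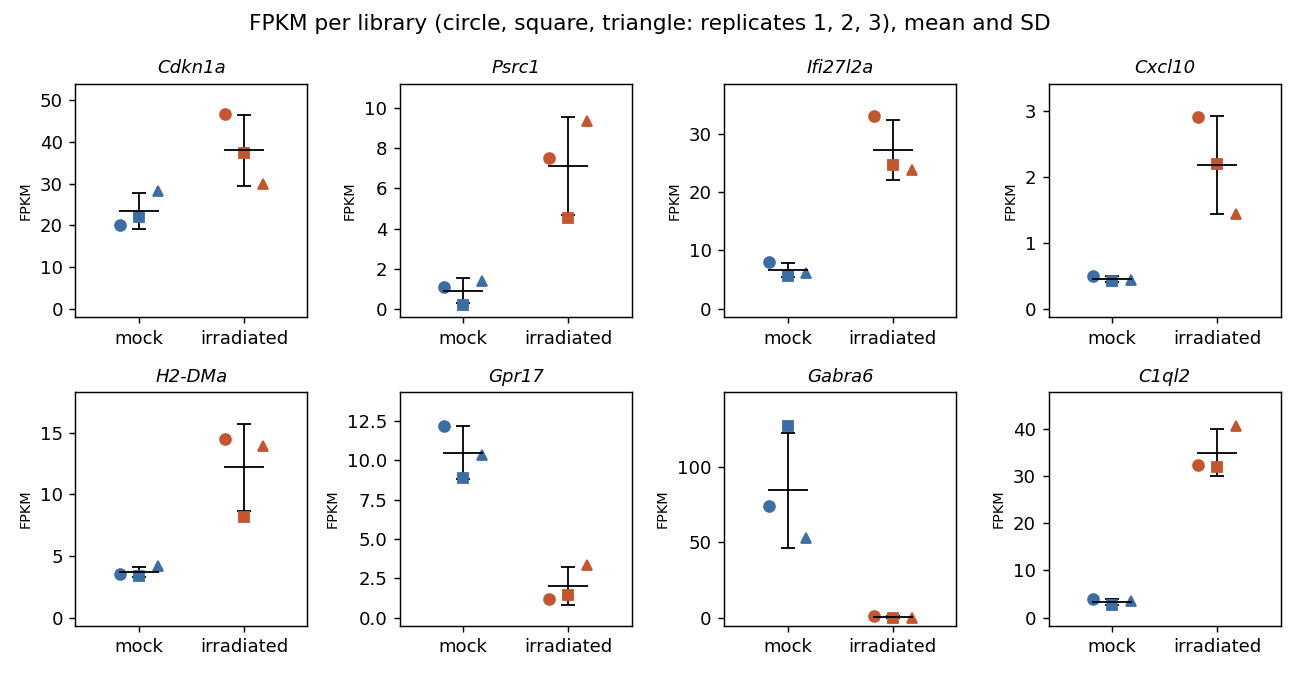
Points are FPKM of 8 genes in each library (shapes are replicates 1, 2 and 3), with the mean and SD of 3 libraries per group, on linear axes. Cdkn1a libraries lie between 20.0 and 46.8 FPKM with the groups close together, whereas C1ql2 lies at 2.63 to 3.94 FPKM in mock and at 31.9 to 40.7 FPKM in irradiated libraries.

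Genes of the oligodendrocyte lineage were lower. Of 26 oligodendrocyte precursor genes, 8 fell and 1 rose (13 and 1 when adjusted over the list alone), with a median log2 change of -0.52 (camera adjusted p = 2.49e-06, and adjusted p = 0.55 with an estimated correlation; fry adjusted p = 0.042). Gpr17, a receptor of precursors about to differentiate (chromosome 18, 31942999 to 31949890), went from 10.5 ± 1.68 to 1.99 ± 1.20 FPKM (SD, n = 3; log2 change -2.23, SE 0.31, limma adjusted p = 0.0044). Neu4 had a log2 change of -1.61 (SE 0.22) and Enpp6 one of -1.43 (SE 0.20), while Pdgfra, the precursors' growth factor receptor, had one of -0.66 (SE 0.35, adjusted p = 0.27; from -1.07 without irradiated 3 to -0.29 without irradiated 1). Of 28 myelin and mature oligodendrocyte genes, 6 fell and 0 rose (26 fell when adjusted over the list alone), with a median of -0.79 (camera adjusted p = 5.25e-10, and adjusted p = 0.63 with an estimated correlation). Ugt8a, an enzyme of myelin lipid synthesis, had a log2 change of -1.49 (SE 0.29), not called without mock 1 or mock 2 (adjusted p up to 0.073). The choroid plexus list had 2 of 22 lower and 0 higher (2 lower when adjusted over the list alone; median -0.49, camera adjusted p = 0.00028, and adjusted p = 0.71 with an estimated correlation), with Kcne2 at -1.56 (SE 0.26). By library the choroid plexus median was 0.49, -0.22 and 0.50 in mock and -0.48, -0.26 and -0.052 in irradiated libraries, so mock 2 lay below irradiated 3. The endothelium list had 1 of 34 lower, Ocln, and 0 when adjusted over the list alone (median -0.30, camera adjusted p = 0.047, and adjusted p = 0.79 with an estimated correlation). It passed in 13 of 18 settings, and not without mock 1, mock 3 or irradiated 1 (adjusted p = 0.18, 0.063 and 0.59, the last with a median of -0.089), with library weights (0.083) or without mock 2 and irradiated 1 (0.20). Its library medians were 0.31, -0.070 and 0.16 in mock and -0.48, 0.068 and 0.044 in irradiated libraries, so irradiated 2 and 3 lay above mock 2. Ocln was not called without any 1 of the libraries. The brainstem and cerebellar markers above were lower in the same libraries.

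The astrocyte, astrocyte reactivity and newborn neuron lists did not pass the list test with all 6 libraries. The astrocyte and newborn neuron lists passed in some alternatives, whereas the astrocyte reactivity list passed in 0 of 18 settings. Gfap, the astrocyte filament protein, was at 228 ± 73.9 FPKM in mock and 271 ± 38.1 FPKM in irradiated libraries (SD, n = 3; limma adjusted p = 0.50), and Vim at 91.7 ± 32.2 and 54.1 ± 10.8 FPKM (adjusted p = 0.13). The astrocyte list had 1 of 30 higher and 3 lower (the same counts when adjusted over the list alone; camera adjusted p = 0.21) and passed in 3 of 18 settings (smallest adjusted p = 0.0049). The astrocyte reactivity list had 4 of 33 higher and 1 lower (likewise; camera adjusted p = 0.24). Of 30 newborn neuron and progenitor genes, 5 fell and 0 rose (5 fell when adjusted over the list alone; camera adjusted p = 0.18). The list passed in 5 of 18 settings, without mock 2 for example (median -0.74, adjusted p = 0.00024). By library its median was 0.53, -0.43 and 0.53 in mock and 0.14, -0.31 and -0.20 in irradiated libraries, beside 0.68, -0.76 and 0.79 and 1.10, -0.78 and -0.66 for the olfactory bulb list. Neurod1, also a cerebellar granule cell gene, fell from 53.6 ± 11.6 to 5.64 ± 0.33 FPKM. Dcx, a marker of newborn neurons, was at 5.38, 0.87 and 3.40 FPKM in mock and at 1.498, 1.48 and 1.28 FPKM in irradiated libraries (adjusted p = 0.36). Without mock 2 its log2 change was -1.32 (adjusted p = 0.028, and 0.40 to 0.76 without each other library).

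Immediate early genes were higher, with 3 of 32 called higher and 1 lower (8 and 1 when adjusted over the list alone; median 0.55, camera adjusted p = 5.34e-05, and adjusted p = 0.69 with an estimated correlation). The list median ranged from 0.28 to 0.76 over 18 settings. By library it was -0.14, -0.66 and 0.12 in mock and 0.15, 0.36 and 0.46 in irradiated libraries, relative to the mean of all 6, and mock 2 was also the lowest on the excitatory neuron list (-0.77). Nr4a2, a nuclear receptor that midbrain dopamine neurons also express, had a log2 change of 1.80 (SE 0.27), Nr4a3 one of 1.605 (SE 0.22), and Dusp5, a phosphatase, one of -1.58 (SE 0.16). The glucocorticoid-responsive list had 1 of 22 higher and 0 lower (1 higher when adjusted over the list alone; median 0.36, camera adjusted p = 0.0065, and adjusted p = 0.72 with an estimated correlation), and did not pass without mock 1 or irradiated 2 (adjusted p = 0.13 and 0.051). Its library medians were -0.44, -0.059 and 0.074 in mock and -0.16, 0.33 and 0.37 in irradiated libraries, so irradiated 1 lay below mock 2 and mock 3. The ribosomal protein list had 0 of 50 members called in limma (2 higher and 0 lower at an unadjusted p under 0.05), but 47 of them had positive values and the median was 0.42 (camera adjusted p = 5.34e-05, and adjusted p = 0.72 with an estimated correlation; adjusted p = 0.17 after quantile normalization and 0.15 without mock 2 and irradiated 1). By library the ribosomal protein median was -0.40, -0.34 and 0.09 in mock and 0.57, -0.21 and 0.22 in irradiated libraries, so the groups overlapped. The other 28 lists tested had adjusted p from 0.052 to 0.97. Of these, heat shock and protein folding passed in 7 of 18 settings, pan-neuronal genes in 6, monocytes, neutrophils and border macrophages in 4 and nuclear-encoded oxidative phosphorylation genes in 2. Over 18 settings the median ranged from 0.38 to 0.67 for the MHC class I list, 0.32 to 0.59 for homeostatic microglia, 0.12 to 0.22 for p53 targets, 0.19 to 0.54 for glucocorticoid-responsive genes, 0.11 to 0.60 for ribosomal proteins and -0.71 to -0.38 for the choroid plexus.

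**Figure D3:**
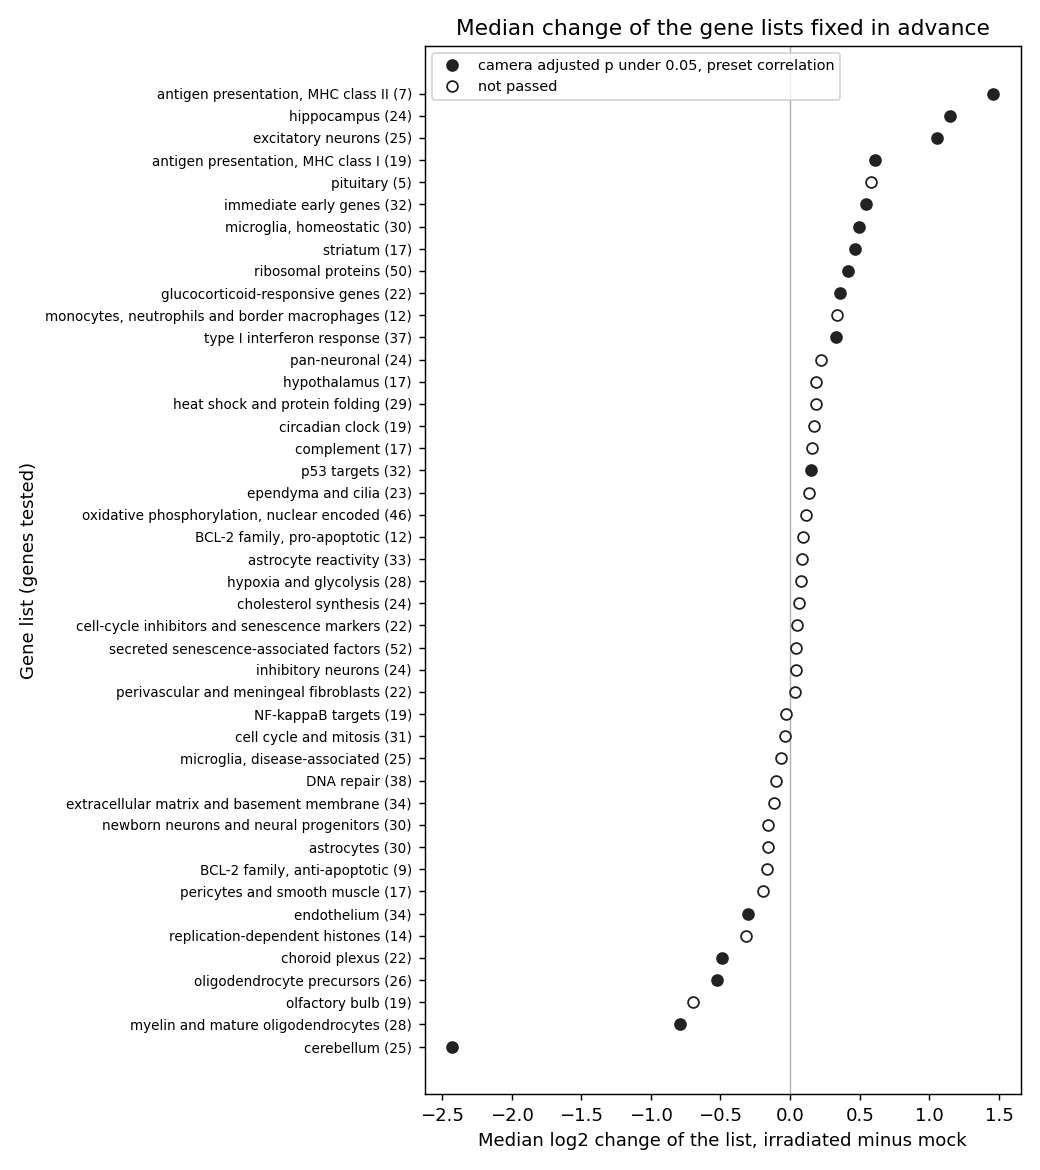
Each point is the median log2 change of a list, irradiated minus mock, with the number of genes tested in brackets; filled points passed camera at an adjusted p under 0.05 with the preset correlation. The cerebellum list (-2.43) lies farthest from 0.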

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

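The covariate, the length and GC correction and the joint removal of mock 2 and irradiated 1 were chosen after the data were seen. The other alternatives were fixed in advance. All 1126 called genes kept their sign in every alternative that tested them, but the number of calls depended on the libraries. For most alternatives the sign could not change, because every called gene had its irradiated libraries outside the mock range. That holds for leaving out libraries and for changes of the pseudocount, the filter or the library weights. Leaving out each library gave 147 to 673 genes higher and 254 to 695 lower, 11 to 14 lists higher and 4 to 7 lower. With library weights 863 and 976 genes were called, with an adjusted p under 0.1 1002 and 1149, with the telencephalic covariate 201 and 297, and with the length and GC correction 864 and 909. Median centring gave 598 higher and 596 lower, and quantile normalization 643 and 626, so the excess of lower genes depended on the scaling. Equal replicate numbers showed no sign of pairing the mice: deviations from the group means correlated at -0.33, 0.19 and 0.20 between equally numbered libraries and mock 1 and mock 3 correlated best with another number. With the replicate block 401 genes were higher and 394 lower. With an estimated correlation 0 lists were higher and 0 lower, and fry gave 3 and 2. The p53 targets (median 0.15) and interferon (median 0.33) lists lost their camera calls with estimated correlations of 0.015 and 0.13. The value for p53 targets was near the preset 0.01, so its size alone does not account for that lost call. The cerebellum list did not pass with this option either (camera adjusted p = 0.55), so the option cannot tell the lists apart here. The median of the secreted senescence-associated factors was 0.05 and turned to -0.025 with the covariate and ranged from -0.020 to 0.11 without each library. That of the cell cycle list turned to 0.053 without a filter and 0.079 after quantile normalization. Among uncalled genes, Bcl2 turned to 0.13 after quantile normalization and 0.23 with the length and GC correction and ranged from -0.13 to 0.11 without each library. Mdm2 turned to 0.00077 with that correction. Gdf15 turned to 0.032 without mock 2 and irradiated 1 and ranged from -0.49 to 0.078 without each library. Cdkn2b ranged from -0.34 to 0.037. Cdkn1a did not reach an adjusted p under 0.05 in any alternative and ranged from 0.52 to 0.84 without each library. The causes were not tested. Depth per gene is unknown. By the filter fixed in advance, genes with a mean under 0.5 FPKM over the 6 libraries were not tested in the main comparison.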

Other observations

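The tests of explanations in this part were all chosen after the results were seen. Cartpt, a neuropeptide of hypothalamic and midbrain neurons, was at 15.8 ± 5.33 FPKM in mock and 95.9 ± 39.7 FPKM in irradiated libraries (SD, n = 3; log2 change 2.52, SE 0.37, limma adjusted p = 0.0060), and Ucn, a peptide of the CRH family found in the midbrain, was at 1.64 ± 1.10 and 20.4 ± 4.65 FPKM. The hypothalamus list, which holds Cartpt, did not pass (camera adjusted p = 0.24). Dio3, which inactivates thyroid hormone, was at 0.50, 0.11 and 0.40 FPKM in mock and at 8.32, 5.98 and 13.2 FPKM in irradiated libraries. Nrep fell from 191 ± 39.4 to 29.6 ± 10.6 FPKM.

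Eda2r, a p53 target with too little RNA for the test and chosen after its values were seen, was at 0.11, 0.13 and 0.09 FPKM in mock and at 0.32, 0.44 and 0.35 FPKM in irradiated libraries. Without a filter its log2 change was 0.50 (limma adjusted p = 0.022).

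Cerebellar and hindbrain genes were lower in all irradiated libraries. A selective loss of cerebellar granule cells as the whole cause is argued against by the Hox genes, which those cells do not express: all 16 Hox genes tested fell, with a median log2 change of -2.58 (SD 0.84 between genes). Irradiation was the same within a group, yet region markers differed there. The telencephalon list lay at -3.09 in mock 2 and at 0.54 and 0.47 in mock 1 and mock 3. The olfactory bulb output neuron list lay at 1.46 in irradiated 1 and at -1.43 and -1.58 in irradiated 2 and 3. These values argue against irradiation as the only source of regional differences between libraries. Whether regional makeup also accounts for the hindbrain difference between groups cannot be told apart from irradiation. The lowest mock library lay 2.28 above the highest irradiated one on the cerebellum list, so no libraries of the groups match. A loss of several hindbrain cell types after irradiation stays open as well and was not tested.

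The interferon, MHC class I and homeostatic microglia lists were higher. After the length and GC correction the interferon list kept 127.9% of its median change over its 37 tested members (95% range over resampled genes 84.5% to 212.4%). This argues against those trends as the cause of that list's median change. Among its called genes, Oasl2 went from 1.04 to 1.07 and the others shrank, Ifi27l2a from 1.96 to 1.64 for example. Zbp1 lost its call (limma adjusted p = 0.056). Oasl2 and Zbp1 were chosen after their values were seen. The MHC class I list kept 62.0% (58.5% to 98.0%) and the microglia list 77.0% (57.3% to 215.5%), so a part played by such trends stays open there, although both lists still passed camera (adjusted p = 0.0026 and 3.29e-05). Unequal regional makeup as the cause cannot be told apart from irradiation, because the groups lay 2.28 apart on the cerebellum list with no overlapping libraries. With the telencephalic covariate the 19 called genes of these lists kept 82.8% of their median change, and 5 of them stayed called. That covariate does not decide the question, as no libraries of the groups match.

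The ribosomal protein list was higher, at a median of 0.42. Trends with transcript length differed between libraries, with Spearman correlations of a gene's deviation with length from -0.56 in irradiated 1 to 0.48 in mock 1. After the length and GC correction 39.9% of the median was left (95% range over resampled genes 28.1% to 51.1%), at 0.17 (camera adjusted p = 0.018; range over 18 settings 3.94e-08 to 0.17). Such trends may account for part of the change, and irradiation stays open.

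The real grouping called 1126 genes, and the highest of the other splits of the 6 libraries called 12; 1 of the 10 splits called as many genes. It called 16 lists, and the highest of the other splits called 18; 4 of the 10 splits called as many lists. With 10 splits a share under 0.05 cannot be reached.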
